A study of Mus musculus with 2 samples.

How the data were processed

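Dimethylation of histone H3 at lysine 4 (H3K4me2), a mark of active and poised promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the embryonic facial prominence of mice at 14.5 days of gestation. Per the labels, the 2 samples are biological replicates of 1 group. Replicate 1 was pooled from 24 embryos and replicate 2 from 34, with both sexes mixed and a fragment size range of 300 to 500 bp. The group and the replicate numbers were taken from the labels. There was no second condition, so no comparison between conditions was made, and the spread between these 2 pools is the only replicate error.

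4 peak lists on the mouse assembly mm10, named in the labels, were used: one for each replicate, one called on both replicates pooled, and one of replicated peaks. Per the labels and the accompanying text files, each replicate's peaks came from its own alignments and its own control library, and the replicated list was derived from the other 3. The aligner, the peak caller, the thresholds and the rule behind the replicated list are not given in the sources used here. The deposited signal value of a peak has no stated definition, so it was used only to rank and describe peaks within a list. The deposited score, a rescaled integer per peak, was not used in any test. The deposited −log10 p and −log10 q of each peak come from the submitters' peak calling and served as a stricter filter, at a −log10 q of at least 3. The lists give no read counts, so the sequencing depth is unknown and no counting intervals were computed.

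Peaks on the 21 assembled chromosomes (the autosomes, X and Y) were analysed. Gene models were GENCODE M21 on GRCm38, the same assembly, and all peaks ended within its chromosome lengths. The annotation gave 21829 protein-coding genes with 54322 distinct transcription start sites (TSSs). A promoter was called marked when a peak came within 1 kb of any TSS of a protein-coding transcript of the gene. A peak was assigned by its midpoint to the promoter, exon, intron or intergenic class. Promoters were placed in 3 CpG classes by the observed over expected CpG ratio within 500 bp of a TSS: low under 0.4, high from 0.65, intermediate between. The highest ratio among a gene's TSSs was used, so a gene with many TSSs was more likely to be classed high. Covered length is the number of bp in peaks within 5 kb of a gene's TSSs. Overlapping windows of a gene were merged, so a gene with a single TSS could reach at most 10001 bp and one with spread TSSs more. Covered length was computed from each replicate's list and from the replicated list. A distal peak lay over 2 kb from every protein-coding TSS and was assigned to the gene with the nearest TSS, which is a convention and not a measured target. For domains, peaks were joined over gaps of up to 1 kb, and the widest 5% of domains holding a TSS were called wide.

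The tests, the processing alternatives, 19 gene lists and the rule for naming genes were fixed before the data were examined. The correlations of Hox paralog number with covered length were not among these fixed tests. Overlap between replicates was the share of peaks sharing at least 1 bp with a peak of the other replicate. It was set against 1000 circular shifts of the other list within each chromosome (one-sided permutation share, smallest possible p = 0.001). Gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes for marked promoters, and against all other marked genes for wide domains. Distal peaks per gene were tested against 10000 random lists matched on list size and on the decile of territory length, the stretch nearer to a gene's TSSs than to any other (two-sided permutation, smallest possible p = 0.0002). Each family was adjusted over its 19 lists by the Benjamini-Hochberg method, at a threshold of 0.05. Genes are not independent replicates, and the p-values describe lists within this tissue. Of 478 symbols listed by name, 1 (Ahsp) was not found in the annotation.

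Named genes were the 20 in the widest domains, the 10 with the most distal peaks, and for each list up to 3 members with the longest covered length and up to 3 without a marked promoter, alphabetically. The 5 replicated peaks with the highest signal were also named. Lists of minor interest were named in part. Other genes are named only where stated as chosen after their values were seen.

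Alternatives were each replicate's own list, the pooled list, the −log10 q filter, overlaps of 50% of either or of both peaks, promoter windows of 500 bp and 2 kb, and the most upstream TSS alone. Others were an exact stratified test over CpG classes, a distal distance of 5 kb, random lists without territory matching, no joining or joining over 3 kb, and the widest 10%. A background without olfactory and vomeronasal receptor genes was added after the data were seen. So was a stratified test of wide domains over deciles of the CpG count within 5 kb of the TSS. That count was the highest among a gene's TSSs. The background without receptor genes was used with Fisher's exact test only, so the tests over CpG classes kept these genes.

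The log2 ratio of covered length between the replicates, with 500 bp added to each value, was also chosen after the data were seen. It was taken over the 15672 genes with coverage in either replicate, and a list's median was placed among 10000 random lists matched on covered length, as a description of these 2 libraries without a p-value.

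The steps were tested on simulated data. For the replicate overlap, a planted share of 69.7% was recovered as 72.1%. Among 19 simulated lists of 30 genes each, drawn from 21829 genes, all 5 lists with raised and all 5 with lowered promoter marking were called, and 0 of 9 unchanged ones. These planted changes were large and were scored at a single TSS per gene without a window. The rule of any TSS within 1 kb was not itself simulated. For wide domains, 5 of 5 lists with 4-fold wider peaks were called and 0 of 14 others. For distal peaks, 5 of 5 lists planted at 4-fold and 2 of 5 planted at 2-fold were called, and 0 of 9 unchanged ones. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0, and figures used matplotlib 3.10.9.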

Results

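H3K4me2 was mapped in the facial prominences of mouse embryos at 14.5 days of gestation, when the palate, jaw skeleton, teeth and facial epithelium are forming. The tissue is mainly mesenchyme derived from neural crest, with epithelium, muscle, nerve and vessels. The data comprised 2 biological replicates, pools of 24 and 34 embryos. Replicate 1 had 50410 peaks on the assembled chromosomes, with a median width of 609 bp, covering 52.5 Mb or 1.92% of the genome. Replicate 2 had 54065 peaks with a median width of 522 bp, covering 49.1 Mb. The pooled list held 56288 peaks over 60.8 Mb and the replicated list 38163 peaks over 55.8 Mb, with a median width of 1048 bp. Read depth is unknown.

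How far the 2 pools gave the same map was measured first. Of the peaks of replicate 1, 76.2% (38407 of 50410) overlapped a peak of replicate 2. In the other direction the share was 78.9% (42666 of 54065). Circularly shifted peaks overlapped at 3.63% and 3.54% on average, so the observed shares were 21 and 22.3 times higher (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The shifts do not keep peaks at promoters. They compare with random placement only and do not test for sharing particular to this tissue. Peaks within 1 kb of a TSS were shared most, at 94.1% and 96.2%, and those farther away at 65.2% and 67.9%. The share was higher among peaks of higher signal. In replicate 1 it was 42.4% and 39.2% in the 2 lowest deciles of the signal value and 80.3% in decile 5. From decile 8 to 10 it was 100% in both replicates. Median peak width rose as well between deciles 1 and 10, from 224 to 2193 bp in replicate 1 and from 205 to 1940 bp in replicate 2. Signal and width were not separated.

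**Figure D1:**
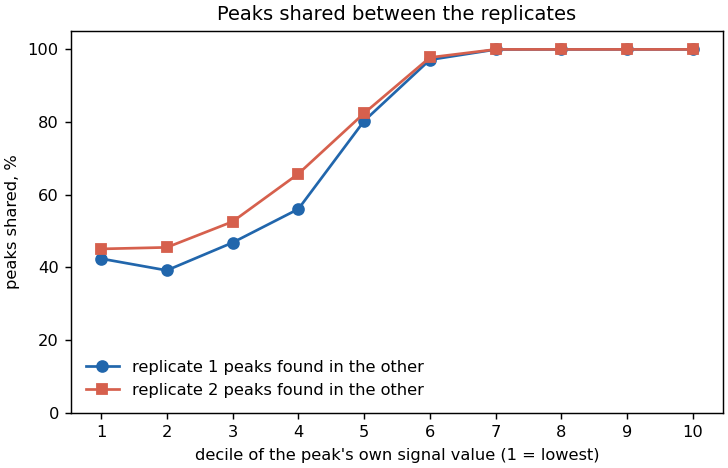
Share of each replicate's peaks (vertical axis, %) that overlapped a peak of the other by at least 1 bp, by decile of the peak's own signal value within its list (horizontal axis). Circles are replicate 1 and squares replicate 2; both lines rise from under 50% in decile 1 to 100% in deciles 8 to 10.

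The replicated list was compared with the lists behind it. Of the 56288 pooled peaks, 34630 overlapped a peak of both replicates by at least 1 bp, and 34501 of these were in the replicated list. At 50% of either peak, 34444 pooled peaks overlapped both, and all 34444 were in the replicated list, where they made up 90.3% of the 38163. The other 3719 replicated peaks were weaker and farther from genes, with a median signal of 3.69 against 15.8 and a median width of 410 bp. Among them 2468 overlapped replicate 1 only and 1139 replicate 2 only, and 112 overlapped neither at this limit. Only 8.98% of them lay within 1 kb of a TSS, against 48.6% of those found in both.

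The mark was concentrated at promoters. By midpoint, 39.5% of replicated peaks lay in promoters, 16.2 times the 2.44% of the genome that promoters occupy. The replicates' own lists gave 34.4% ± 0.66 (SD, n = 2). Exons held 5.39% of replicated peaks, 1.79 times their share of the genome. Introns held 25.7% and intergenic sequence 29.4%, which were 0.747 and 0.490 times their genome shares. Distal peaks, over 2 kb from any protein-coding TSS, numbered 19756 or 51.8% of the list. The promoter share depended on the list and on the window, reaching 29.0% in the pooled list and 27.0% with a 500 bp window.

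Of 21829 protein-coding genes, 14739 (67.5%) had a marked promoter, and the replicates gave 67.8% ± 0.28 (SD, n = 2). Both replicates gave the same call for 98.6% of genes. The share differed widely between CpG classes. Marking reached 98.97% of genes with high-CpG promoters (10016 of 10120), 86.8% with intermediate (3508 of 4040) and 15.8% with low-CpG promoters (1215 of 7669). The receptor genes of the olfactory and vomeronasal systems, expressed in sensory neurons of the nose, were the extreme case, with 5 of 1417 marked. Of these receptor genes, 1405 had low-CpG promoters. Vmn1r4, one of the 5, has a high-CpG promoter on chromosome 6 with 2.53 kb covered in the replicated list.

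Gene lists for the face were marked without exception. All 38 transcription factors of facial mesenchyme and neural crest, all 44 genes of facial growth signalling and all 40 orofacial cleft genes had a marked promoter in the replicated list and in each replicate. Other genes stood at 67.5% (Fisher's exact test, adjusted p = 2.63e-06, 3.75e-07 and 1.21e-06). Within CpG classes the mesenchyme and cleft lists stayed above other genes (exact stratified test, adjusted p = 0.0381 and 0.00481). For the growth signalling list 42.5 marked genes were expected from its CpG classes alone, so close to 44 that this test could not have placed it above other genes (0.530). The 3 most covered mesenchyme factors were Nr2f2, a nuclear receptor, Satb2, a chromatin organiser mutated in cleft palate, and Tfap2a, a neural crest regulator. Their covered lengths were 15.2 ± 1.3, 15.3 ± 0.45 and 14.6 ± 0.46 kb (mean ± SD, n = 2). In the signalling list Fgfr2, an FGF receptor of palate and skull, had 15.6 ± 0.24 kb. The Hedgehog receptor gene Ptch1 had 14.6 ± 0.21 kb and the Wnt ligand gene Wnt5a 12.6 ± 0.0057 kb. A gene's covered length also depends on the number and spread of its TSSs, so these rankings do not rank mark strength alone. The gene model of Fgfr2 runs from 130162451 to 133123350 on chromosome 7, so its windows may lie far apart.

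All 25 genes of surface and oral epithelium were marked in both replicates (Fisher's exact test, adjusted p = 0.000270). The list was well above its CpG expectation too. 10 of its members have low-CpG promoters, and 15.7 marked genes were expected (exact stratified test, adjusted p = 2.47e-08). Covered lengths were moderate: 6.84 ± 1.5 kb at Cldn6, a tight junction gene, 4.88 ± 0.65 kb at the splicing factor gene Esrp1 and 4.59 ± 0.098 kb at Grhl2 (mean ± SD, n = 2). The median log2 ratio of covered length in replicate 1 over replicate 2 was -0.12 for this list, against 0.07 for all genes with coverage.

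In the cartilage list 18 of 22 promoters were marked and in the bone list 14 of 22. Neither differed from other genes in the Fisher's exact test (adjusted p = 0.198 and 0.657), but both lay above within CpG classes (exact stratified test, adjusted p = 0.00685 and 0.00680). For bone this was a change of direction, since 16 of its members have low-CpG promoters. Sox9, the master regulator of cartilage, had 7.18 ± 0.63 kb covered and Sox6, its partner, 12.7 ± 0.98 kb. Runx2, the master regulator of bone, had 13.9 ± 0.82 kb and the collagen gene Col1a1 8.45 ± 0.15 kb (mean ± SD, n = 2). The unmarked promoters included Col10a1, a collagen of hypertrophic cartilage, and Bglap, Bglap2 and Dmp1, genes of mature bone cells. Dmp1 was marked in the pooled list only. The cartilage list had more coverage in replicate 1 than in replicate 2, with a median log2 ratio of 0.34.

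Muscle, blood and liver lists were marked less often than other genes. Skeletal muscle had 10 of 25 promoters marked (Fisher's exact test, adjusted p = 0.00781). This call was lost in the replicates' own lists, which marked 56.0% and 48.0% (Fisher's exact test, adjusted p = 0.227 and 0.0756). It was lost too in the pooled list (0.207), with a 2 kb window (0.110) and within CpG classes (0.798). Pax7, a factor of muscle stem cells and also of neural crest, had 6.71 ± 0.89 kb covered, whereas the actin genes Acta1 and Actc1 had unmarked promoters. The muscle list had a median log2 ratio of replicate 1 over replicate 2 of 0.57.

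In the macrophage and leukocyte list 4 of 21 promoters were marked, in the erythroid list 4 of 17, and in the liver, gut and pancreas list 8 of 29. All 3 lay below other genes (Fisher's exact test, adjusted p = 2.60e-05, 0.000482 and 3.87e-05). Their low-CpG members numbered 18, 14 and 20. Within CpG classes none of the 3 differed from other genes (exact stratified test, adjusted p = 0.631, 0.798 and 0.0838). The 7669 low-CpG genes include 1405 receptor genes, which lower the expected counts, and this test was not run without them. A lack of difference is therefore not shown. Runx1, a blood factor also used in skeletal and epithelial tissue, had 8.80 ± 0.39 kb covered (n = 2). Adgre1, Aif1 and C1qa of macrophages, Alas2, Epb42 and Gata1 of red cells, and Afp, Alb and Apoa2 of liver had unmarked promoters in the replicated list and in both replicates. Alb was marked in the pooled list.

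Pluripotency and germ line genes were marked in 8 of 26 cases (Fisher's exact test, adjusted p = 0.000361). The list stayed low within CpG classes, where 19.5 marked genes were expected (exact stratified test, adjusted p = 8.91e-11). Ddx4, a germ cell RNA helicase gene, has a high-CpG promoter that was not marked in the replicated list, though replicate 1 had a peak over 241 bp near it. Dppa3 was likewise unmarked except in replicate 2, with 236 bp, and both genes were marked in the pooled list. Dppa2, another gene of early embryo and germ cells, was unmarked in all 4 lists. The receptor list, at 0.353%, also remained below its CpG expectation of 233.1 genes (exact stratified test, adjusted p = 6.03e-117).

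Neuronal genes were marked in 24 of 27 cases and transcription factors of forebrain and eye in 18 of 20 (Fisher's exact test, adjusted p = 0.0314 and 0.0427). Both calls were lost within CpG classes (exact stratified test, adjusted p = 0.369 and 0.631, the second with the direction turned). Both were lost against a background without receptor genes (Fisher's exact test, adjusted p = 0.0812 and 0.116). Each replicate's own list marked 96.3% of the neuronal genes, against 88.9% in the replicated list. Isl1, a factor of cranial motor and sensory neurons, had 5.83 ± 0.52 kb covered, and the brain and eye factors Six3 and Lhx2 had 8.86 ± 2.0 and 8.36 ± 2.0 kb (mean ± SD, n = 2). The median log2 ratio of replicate 1 over replicate 2 was 0.27 for the neuronal and 0.15 for the forebrain and eye list. The 20 transcription factors of heart, kidney, lung and thyroid were all marked (Fisher's exact test, adjusted p = 0.000873), as were 25 of 25 housekeeping genes (0.000270). With the most upstream TSS alone the former call was lost (Fisher's exact test, adjusted p = 0.0931). Within CpG classes the organ list stayed above other genes, with 17.4 marked genes expected (exact stratified test, adjusted p = 0.0367). For housekeeping genes 24.3 of 25 were expected within CpG classes, so that test could not have placed the list above other genes. The organ list shares Isl1 with the neuronal list and Emx2 with the forebrain and eye list. Schwann cell and glia genes (13 of 15) and endothelial genes (17 of 22) did not differ from other genes (Fisher's exact test, adjusted p = 0.198 and 0.394). Within CpG classes the Schwann list lay above (exact stratified test, adjusted p = 0.0134). The endothelial list had a median log2 ratio of 0.20 between the replicates.

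**Figure D2:**
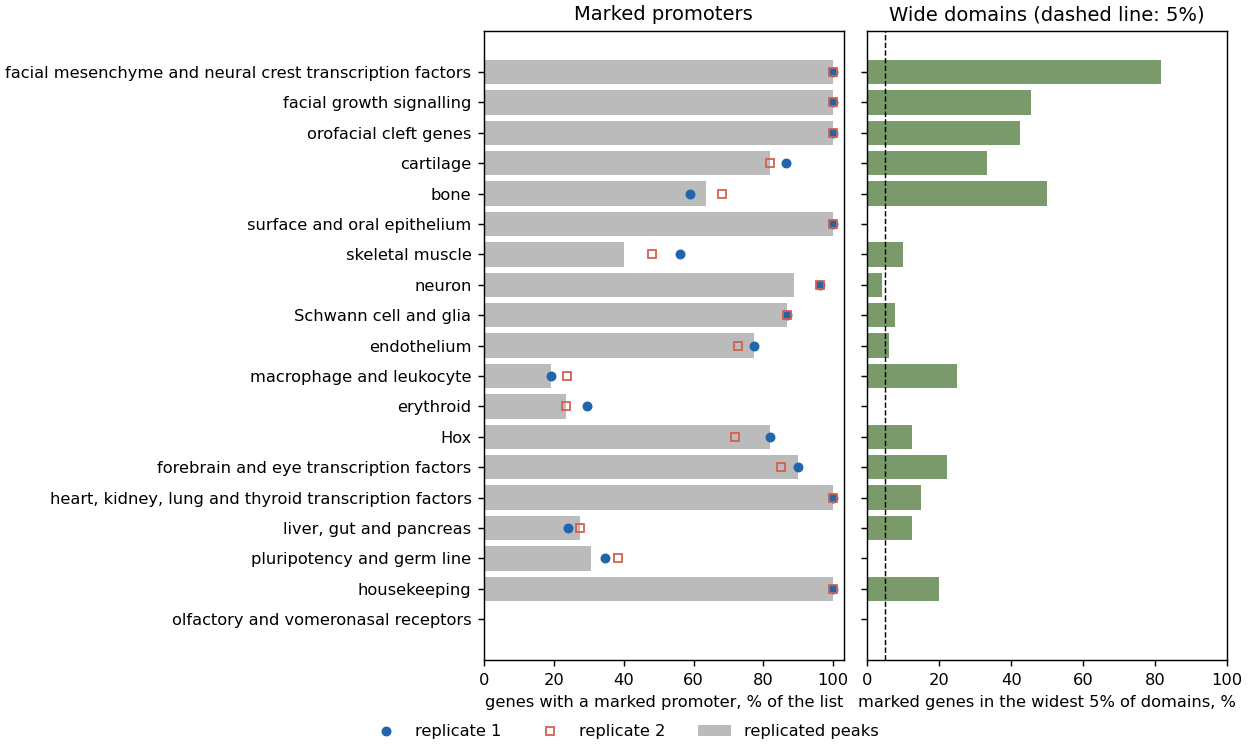
Left, share of each list's genes with a marked promoter (%), with bars for the replicated list, circles for replicate 1 and squares for replicate 2 (no replicate points for the receptor list, whose bar is 0.353%). Right, share of each list's marked genes in the widest 5% of domains (%), where the facial mesenchyme list reached 81.6%.

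Hox genes pattern the body behind the face, and the facial prominences form mostly in front of their expression. Of 39 Hox promoters, 32 were marked, 82.1% in replicate 1 and 71.8% in replicate 2. The list did not differ from other genes (Fisher's exact test, adjusted p = 0.0751). It lay above with the pooled list and a 2 kb window (0.0499 and 0.00463), and below its CpG expectation of 35.5 (exact stratified test, adjusted p = 0.0495). Coverage declined from anterior to posterior paralogs. The correlations that follow were not among the tests fixed beforehand. Spearman's rho between paralog number and covered length was -0.75 across 39 genes (permutation p = 1e-05, the smallest that 100000 permutations can give). Pearson's r was -0.55 (permutation p = 1e-05), and -0.58 without the 2 genes farthest from the median paralog number. Within the clusters rho was -0.85 for HoxA and -0.61 for HoxB (permutation p = 0.00174 and 0.0675), and -0.62 for HoxC and -0.75 for HoxD (exact permutation p = 0.0857 and 0.0255). Over the 10 relations computed, the adjusted p was 2.5e-05 for all Hox genes and 0.00348, 0.0844, 0.0953 and 0.0364 for the 4 clusters. The windows of neighbouring Hox genes overlap and can hold the same peaks: Hoxb7 and Hoxb8 both had 1860 bp in the replicated list. The permutations treat the genes as independent, so these p-values are likely too small. Covered length also depends on the number and spread of a gene's TSSs. The replicates differed here, with rho of -0.78 in replicate 1 (permutation p = 1e-05) and -0.41 in replicate 2 (permutation p = 0.0109, adjusted p = 0.0181). Hoxd3 had 18104 bp covered in replicate 1 and 7861 bp in replicate 2. Hoxb3 had 15214 and 2581 bp, and Hoxa2 had 9964 and 2910 bp. In replicate 1 the HoxB cluster (chromosome 11, 96194316 to 96368256) was covered over 19.6% of its length, and in replicate 2 over 3.91%. The HoxA cluster stood at 29.0% and 12.7%, HoxC at 9.27% and 5.87%, and HoxD at 30.2% and 17.4%. Hoxa9, Hoxb8 and Hoxc11 had unmarked promoters.

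**Figure D3:**
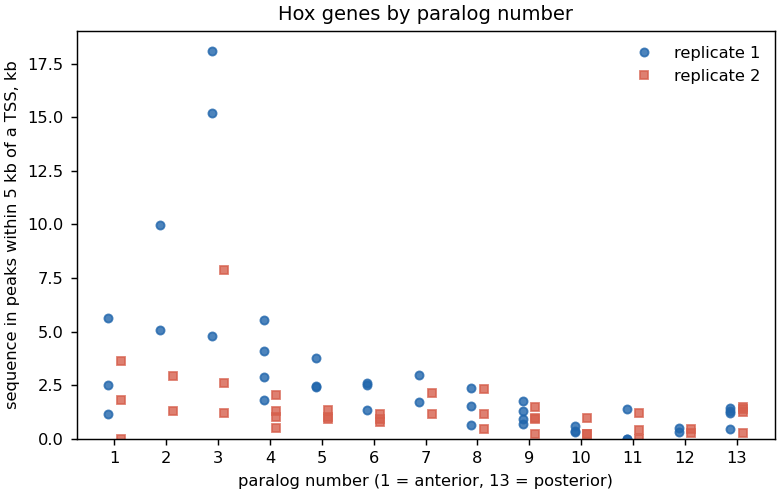
Sequence in peaks within 5 kb of the TSSs of each Hox gene (vertical axis, kb) by paralog number (horizontal axis), with circles for replicate 1 and squares for replicate 2. The highest points are replicate 1 values of paralog 3, and rho was -0.78 in replicate 1 and -0.41 in replicate 2.

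Distal peaks were most frequent around the facial regulators. The mesenchyme transcription factors had 6.71 distal replicated peaks per gene, 3.53 times the 1.90 of random lists with the same territory lengths (permutation, adjusted p = 0.0019). Of the 38 genes, 37 had at least 1. Distal peaks were counted before joining, so a peak inside a wide domain counted as distal where it lay over 2 kb from every TSS. Distal counts and domain widths are therefore not independent measures. The replicates' own lists, which hold more peaks, gave 11.2 ± 1.5 per gene (SD, n = 2). Cleft genes had 4.40 per gene (2.46 times, adjusted p = 0.00253) and growth signalling genes 3.98 (2.00 times, permutation, adjusted p = 0.0076). Lists for organs outside the face were above random lists as well: forebrain and eye factors had 4.40 (3.05 times, permutation, adjusted p = 0.0038) and factors of heart, kidney, lung and thyroid 3.95 (2.345 times, 0.0177). Bone genes had 3 (2.39 times, permutation, adjusted p = 0.0320) and Hox genes 0.564 (2.49 times, 0.0337). The receptor genes lay below, at 0.0438 against 0.406 (permutation, adjusted p = 0.0019). In the replicates' own lists the means were 7.12 ± 0.71 for cleft genes, 6.57 ± 0.80 for growth signalling, 6.08 ± 0.39 for forebrain and eye, 5.1 ± 0.14 for heart, kidney, lung and thyroid, and 4.73 ± 0.13 for bone (SD, n = 2). Hox genes had 1.15 in replicate 1 and 0.641 in replicate 2.

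The other 11 lists did not pass. Cartilage stood at 2.82 per gene (permutation, adjusted p = 0.0654), skeletal muscle at 1.40 (0.0904) and housekeeping at 0.880 (0.0960). Macrophage and leukocyte genes had 1.43 (0.120) and endothelial genes 2.14 (0.137). Cartilage, macrophage, housekeeping and muscle genes stood at 2.14, 2.07, 2.06 and 1.96 times random lists, near the 2.00 times of growth signalling, which passed. In the simulation only 2 of 5 lists planted at 2-fold were called, so these lists are not shown to lack an excess. Epithelium, with 0.960, neuron, with 2.19, and Schwann cell and glia, with 1.80, all had an adjusted p of 0.432. Pluripotency and germ line genes had 0.846 (0.940), and the erythroid list, with 0.353, and the liver list, with 0.828, had an adjusted p of 1. With a 5 kb limit the bone and Hox calls were lost (permutation, adjusted p = 0.0898 and 0.0793), and in the pooled list that of heart, kidney, lung and thyroid (0.0753). Without territory matching Hox lay below random lists (0.375). Without replicate 1 the Hox call was lost (0.142), and epithelium, with 1.32 per gene in replicate 1 and 2.36 in replicate 2, passed (0.0402). Without replicate 2 cartilage passed (0.0130).

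The gene with the most distal peaks was Zfhx3, a zinc finger homeobox gene, with 46 in the replicated list and 71.0 ± 1.4 in the replicates' own lists (SD, n = 2). Adgrl2, an adhesion receptor gene, and Gse1 had 38 each, and Zfp608 had 37. Nfib, a nuclear factor I gene, had 30, the teneurin gene Tenm3 28 and Auts2 25. The ephrin gene Efna5, Nr2f2 and the homeobox gene Pbx1 had 24 each.

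The width of the domain over the TSS set the facial regulators apart from other marked genes. Of the 38 mesenchyme and neural crest factors, 31 (81.6%) lay in the widest 5% of domains, those of at least 5891 bp, against 5.24% of other marked genes (Fisher's exact test, adjusted p = 6.12e-32). The share was 82.9% ± 1.9 in the replicates (SD, n = 2). The 7 outside were Alx3, Dlx3, Dlx4, Hand1, Msx2, Prrx2 and Tbx22, named after their values were seen. Growth signalling had 20 of 44 genes in wide domains (Fisher's exact test, adjusted p = 1.99e-13) and cleft genes 17 of 40 (4.69e-11). The lists share members: 18 cleft genes are in one of the other 2 lists, and these hold 13 of the 17. Of the 22 remaining cleft genes, 4 (18.2%) were in wide domains.

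Of the skeletal lists, 7 of 14 marked bone genes and 6 of 18 marked cartilage genes were in wide domains (Fisher's exact test, adjusted p = 1.60e-05 and 0.00102). Without replicate 1 the cartilage call was lost (0.0519). Forebrain and eye factors had 4 of 18 (Fisher's exact test, adjusted p = 0.0392) and housekeeping genes 5 of 25 (0.0319). Both were lost in replicate 2 alone (0.161 and 0.133) and without joining of peaks (0.576 and 1), where housekeeping lay below other genes. The housekeeping call was also lost in replicate 1 alone (0.0993), in the pooled list (0.105) and with joining over 3 kb (0.848), and the forebrain and eye call among the widest 10% (0.107). Within deciles of the CpG count around the TSS neither passed (exact stratified test, adjusted p = 0.0698 for housekeeping and 1 for forebrain and eye, with 3.87 expected). For housekeeping 1.79 genes were expected and 5 found, so most of its excess remained, at 12.8 points against 14.6 in the main setting. None of the 25 marked epithelial genes lay in a wide domain, which did not differ from other genes (Fisher's exact test, adjusted p = 0.816). The remaining lists, including Hox with 4 of 32 (Fisher's exact test, adjusted p = 0.198), did not pass.

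The widest domain of the replicated list, 28.2 kb on chromosome 5 (119660607 to 119688763, mm10), covered Tbx3, a T-box factor of limb, gland and face. It joined 7 peaks and measured 22.8 ± 0.24 kb in the replicates (SD, n = 2). There the domains at Zfhx3, Nr2f2, Meis2 and Ebf3 were wider, at 27.2 ± 3.4, 25.3 ± 0.40, 24.6 ± 0.038 and 24.4 ± 1.4 kb (mean ± SD, n = 2). In the replicated list Zfhx3 came next with 26.7 kb, then Nr2f2 with 25.9 kb, and Meis2, a homeobox factor needed by cranial neural crest, with 24.7 kb. Trps1, a GATA-type factor mutated in a facial and skeletal syndrome, had 24.1 kb, though 15687 bp in replicate 1 and 24964 bp in replicate 2. Ebf3 had 23.6 kb, Pou3f3 22.1 kb, Ptch1 21.9 kb and Six1 20.9 kb. Dlx1 and Dlx2, neighbouring homeobox genes that pattern the jaws, shared a domain of 20.7 kb on chromosome 2 (71526804 to 71547456). In the replicates its width was 14.5 ± 8.4 kb at Dlx1 and 15.7 ± 6.8 kb at Dlx2 (SD, n = 2), since it was split in replicate 2. Bahcc1 had 19.9 kb, Alx1, a factor of the frontonasal region, 19.6 kb, Zfhx4 19.11 kb, Satb2 18.96 kb, Pax3 18.8 kb and Mn1 18.1 kb. Nfib had 17.7 kb, Tfap2a 17.3 kb and the retinoic acid receptor gene Rarg 16.9 kb, though 8109 bp in replicate 1 and 17310 bp in replicate 2. Of these 20 genes, 9 were in the mesenchyme list.

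**Figure D4:**
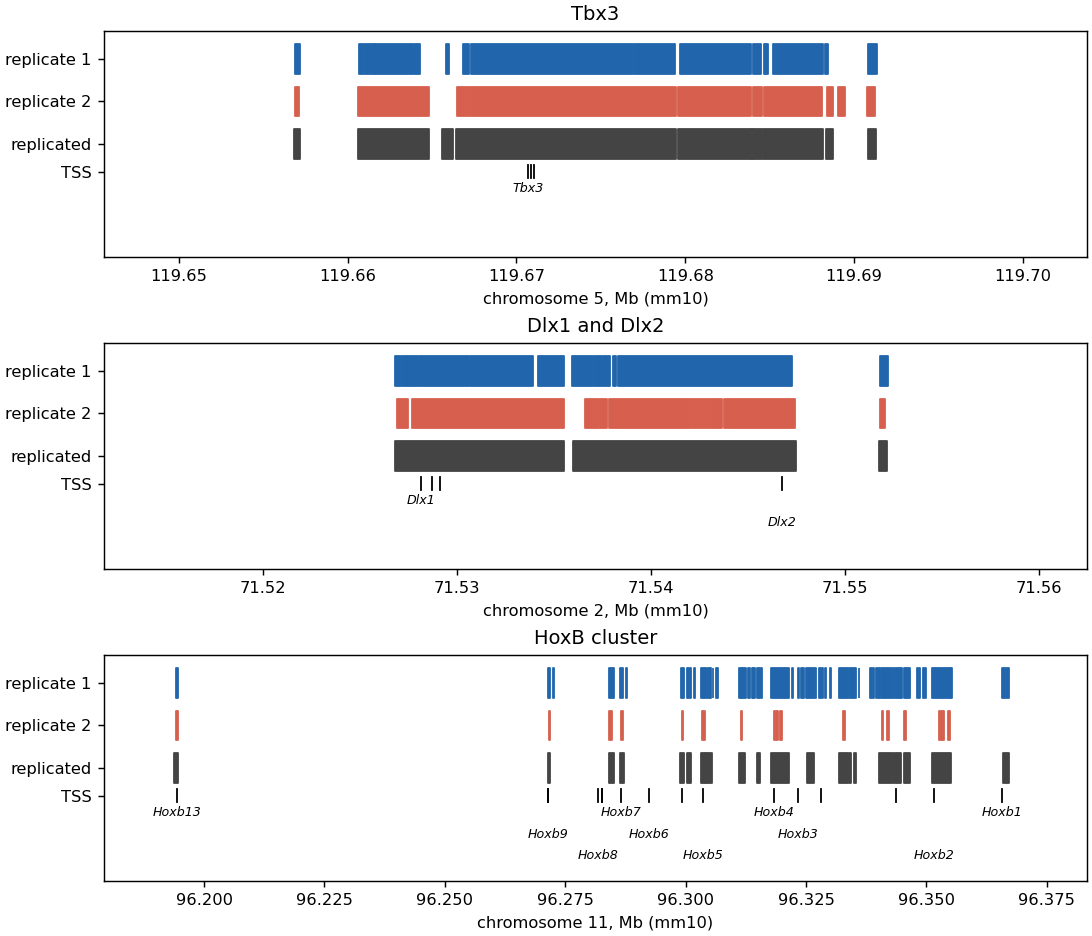
Peaks of replicate 1, replicate 2 and the replicated list (bars) and protein-coding TSSs (ticks) around Tbx3 on chromosome 5, Dlx1 and Dlx2 on chromosome 2 and the HoxB cluster on chromosome 11 (horizontal axes, Mb, mm10). Tbx3 and the Dlx pair were covered alike in both replicates, whereas peaks took up 19.6% of the HoxB cluster in replicate 1 and 3.91% in replicate 2.

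The replicated peak with the highest signal lay at Egr1, an immediate early gene, on chromosome 18 (34859097 to 34863823), with a signal of 74.8. Its summit was 192 bp from the TSS, in an exon. The next were at Prr7 on chromosome 13 (55470776 to 55473682, signal 71.9), Agap1 on chromosome 1 (89579692 to 89583085, 71.7), Trim67 on chromosome 8 (124791803 to 124795055, 70.6) and Rasgef1c on chromosome 11 (49901333 to 49902560, 70.0). The summit at Prr7 lay in an exon 7616 bp from the TSS, and the other 3 lay within 504 bp of theirs. All 5 overlapped peaks of both replicates.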

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

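The replicated list held 11 peaks on scaffolds not placed on an assembled chromosome, which entered none of the comparisons above. They are listed as signal in data outside the main measurement. Such scaffolds are ordinary genomic sequence, so a count above 0 is no surprise in itself. Their signal values ranged from 4.39 to 15.4, at percentiles 20.7 to 54.4 of the replicated list, and 4 of them were on 1 scaffold assigned to chromosome X. No explanation was tested.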

How the results depend on the processing

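The overlap between replicates, the size of the replicated set and most list calls were judged unchanged. For a list call this meant the same side of the threshold, and the same direction where it passed. It held for 143 of 167 values under alternatives for promoter marking, 116 of 126 for distal peaks and 154 of 168 for wide domains. Calls that passed in neither setting counted as unchanged even where the direction turned. Bone promoters, for example, stood at -3.89 points from other genes in the main setting and at 4.10 in the pooled list. The values include counts of passing lists, where 5 against 6 counted as unchanged. The share of peaks found in the other replicate was 60.9% and 56.7% when 50% of both peaks had to overlap, and 79.3% and 84.0% at a −log10 q of at least 3, and the pooled peaks found in both replicates numbered 27676 under the first rule. No paired analysis was possible because there was a single group. Depth is unknown, so its effect on weak peaks could not be measured. Where a result changed, the cause was not tested. The background without receptor genes and the CpG count deciles were chosen after seeing the data.

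The promoter share of peaks was 33.9% to 34.9% leaving out each replicate, 29.0% in the pooled list, 27.0% with a 500 bp window and 46.5% with 2 kb. Marked genes were 67.6% to 68.0%, 68.6% in the pooled list, 66.9% with a 500 bp window, 68.4% with 2 kb and 65.0% with the most upstream TSS alone.

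Adjusted p-values follow. For promoter marking within CpG classes, 3 lists lay below other genes. In that setting growth signalling (0.530) and housekeeping (1), fully marked, had no room to pass. Muscle (0.798), neuron (0.369), macrophage (0.631), erythroid (0.798) and liver (0.0838) lost their calls, cartilage (0.00685) and Schwann cell (0.0134) gained one, and bone (0.00680), Hox (0.0495) and forebrain (0.631) turned direction. Muscle also lost its call without a replicate (0.0756 to 0.227), in the pooled list (0.207) and at 2 kb (0.110). Forebrain ranged from 0.0475 to 0.202, losing its call without replicate 1. Without receptor genes in the background neuron (0.0812) and forebrain (0.116) lost it, and with the most upstream TSS neuron (0.141) and heart, kidney, lung and thyroid (0.0931). Hox passed in the pooled list (0.0499) and at 2 kb (0.00463).

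For distal peaks, leaving out a replicate gave cartilage 0.0130 to 0.0967, epithelium 0.0402 to 0.455 and Hox 0.00076 to 0.142. Cartilage passed without replicate 2, in the pooled list (0.0160) and without territory matching (0.00808), where neuron passed too (0.0422) and Hox turned direction (0.375). Epithelium passed without replicate 1, where Hox lost its call. Over 5 kb, bone (0.0898) and Hox (0.0793) lost theirs, and in the pooled list heart, kidney, lung and thyroid (0.0753).

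For wide domains, 4 to 6 lists lay above leaving out each replicate. Without replicate 1 cartilage (0.00129 to 0.0519) and forebrain (0.00651 to 0.161) lost their calls. Housekeeping lost it without either replicate (0.0993 to 0.133), in the pooled list (0.105), with 3 kb joining (0.848) and within CpG count deciles (0.0698), and turned direction with no joining (1). Forebrain lost it with no joining (0.576), with the widest 10% (0.107) and within deciles (1). The housekeeping excess stayed at 12.8 points within deciles, against 14.6 in the main setting, and fell to 1.7 with 3 kb joining. With 3 kb joining endothelium (0.0458) and heart, kidney, lung and thyroid (0.0187) passed.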

Other observations

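Long non-coding RNA genes were marked at 30.3% of their promoters (3081 of 10155), and at 17.8% (1481 of 8321) once those within 1 kb of a protein-coding TSS were left out. The X chromosome had 5.68 replicated peaks per Mb, against 15.1 on the autosomes together. Marked promoters made up 52.3% of X-linked and 68.8% of autosomal protein-coding genes, a difference that was not tested. Among high-CpG promoters the shares were 96.7% (232 of 240) and 99.04% (9780 of 9875), among intermediate ones 76.2% and 88.0%, and among low-CpG ones 14.7% and 16.3%. Summits of replicated peaks lay in repeat-masked sequence in 7.72% of cases, against 36.4% of the genome.

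The tests in the following paragraphs that were chosen after the result was seen are the erythroid and germ line CpG tests, the CpG count deciles, the comparison of the earlier lists between replicates, and the use of the second epithelial and neural lists against depth or calling.

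The first pattern is a difference between the 2 pools. The median log2 ratio of covered length in replicate 1 over replicate 2 was 0.41 for Hox genes, 0.57 for muscle, 0.34 for cartilage and 0.27 for neurons, all at percentile 100 of 10000 random lists matched on covered length, and -0.12 for epithelial genes, at percentile 0. Endothelial genes (percentile 99.8), forebrain and eye factors (98.7) and factors of heart, kidney, lung and thyroid (97.4) lay high as well, and facial mesenchyme factors (0.230) and growth signalling (1.88) low, with medians of 0.00 and 0.02. Schwann cell and glia genes (13.8) did not go with neurons, nor bone genes (22.1) with cartilage. A different mix of tissues in the dissected pools is a candidate explanation. Lists of 24 other epithelial and 24 other neural genes, none of them in the earlier lists, were written down before their values were seen: the epithelial list lay at percentile 0 (median -0.07) and the neural list at 99.7 (0.17). A difference in depth or calling that acts alike on genes of like coverage would move both the same way, so their opposite places argue against it. One that depends on the kind of gene or peak stays open.

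The most covered genes of the new epithelial list were Tfap2c, with 5763 bp in replicate 1 and 6286 in replicate 2, and Cdh3, with 4552 and 4615. Those of the neural list were Irx5, with 9640 and 9540 bp, and Lmx1b, with 5774 and 5084. In each list 22 of 24 promoters were marked in both replicates, and expression was not measured here. Among genes picked after their values were seen, Hoxb4 had 5539 and 1031 bp in replicates 1 and 2, and Zic4, a factor of neural tube and nearby mesenchyme, 15611 and 3652. Krt17, an epithelial keratin gene, had 0 and 696 bp, and Tnn, a matrix gene, 185 and 2203. With 1 library on each side, a difference in embryo stage within the labelled age or in chromatin preparation stays open and was not tested.

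The second pattern is the width of H3K4me2 domains at the facial mesenchyme and neural crest factors, 31 of 38 of which were in the widest 5%. The CpG count within 5 kb of the TSS, compared in deciles, does not account for it, since 7.10 genes were expected (exact stratified test, adjusted p = 8.70e-18). Domains of the list reached 25.9 kb, so CpG-rich sequence farther from the TSS was not controlled. Differences in CpG count inside a decile were not controlled either. Joining of neighbouring peaks does not either, since 76.3% of the list was among the widest without it. The design has no second tissue, so no biological explanation was tested.

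The third pattern is the low number of marked promoters in several tissue lists. For the macrophage, muscle, liver and erythroid lists, 5.7, 10.96, 11.6 and 4.94 marked genes were expected from CpG classes and 4, 10, 8 and 4 were found, so low CpG content is a candidate explanation. The test cannot tell this from a scarcity of such cells, because low-CpG promoters were not bound to be unmarked. Within CpG classes the epithelial list had 25 marked genes with 15.7 expected, and the bone list 14 with 8.35. Receptor genes, mostly with low-CpG promoters, also stayed in the background and lowered the expected counts. The low counts may or may not reflect how many such cells the tissue held. For pluripotency and germ line genes 19.5 were expected and 8 found, which CpG content does not account for. Promoter DNA methylation in somatic tissue is an untested alternative.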
